A study of Mus musculus with 12 samples.

How the data were processed

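RNA of whole mouse lung was measured on 12 single-colour (Cy3) Agilent 4x44K whole mouse genome arrays, 1 per mouse. Per the labels, the mice were male C57Bl/6 with an age of 12 weeks, and 100 ng of RNA was labelled. The smoke protocol ran for 4 months on 5 days a week per the labels. This is longer than 12 weeks, so 12 weeks cannot be the age at the end of the protocol. The labels call the 4 arrays of each group biological replicates. The groups were wild type (WT) in room air, WT in cigarette smoke, and Rora mutant in cigarette smoke, with n = 4 each. A mutant group in room air was not analysed here, so a genotype effect cannot be separated from an interaction of genotype with smoke. The labels do not state which Rora allele the mutants carried.

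The authors scanned the slides with Agilent Feature Extraction 9.5.3.1, and per the file headers each array's processed signal is an intensity on a linear scale, after background subtraction and detrending within the array, with no normalization between arrays. The raw spot mean and local background in the same files are intensities without any correction, and the flags are other values of 0 or 1. The authors' value table holds log2 intensity; it was checked against the processed signal (lowest correlation of an array 0.99952, 1 common median of 6.79), so its columns were quantile-normalized. Probe positions are those of the files, on mouse build mm8. The 12 arrays lay on 3 slides of 4 arrays each, every slide was scanned separately, and each slide held arrays of all 3 groups. Slide 1 held WT room air replicates 1 and 4, slide 2 WT smoke replicates 2 and 4, and slide 3 mutant smoke replicates 3 and 4. Of the other groups each slide held a single array. Values within a slide thus rest on a single mouse of at least 1 of the groups compared and are no replicated group differences. The depth of an array is given by its signal over background: 70.1% to 74.8% of spots were well above background, and the number of arrays limits the precision.

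From 43379 non-control spots, replicate spots were averaged to 41174 probes, with the scanner's outlier spots left out. Values were log2 processed signal minus the log2 75th percentile of the array. Probes were kept if well above background on at least 4 of the 12 arrays and valued on at least 3 arrays of each group, which left 30191. Symbols were updated through accessions in a RefSeq table (24375 probes by their own accession, 115 by a listed accession), then by symbol or synonym (8625), and 8059 probes kept the name in the file. The kept probe with the highest mean over all arrays represented each gene, which gave 19824 genes, 15665 of them in the RefSeq table. Levels below are log2 units over the array's 75th percentile.

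The 3 comparisons were fitted in 1 model with a mean per group on all 12 arrays (limma 3.58.1 lmFit and eBayes in R 4.3.3; the data.table package, version 1.17.8, held the tables). All tests were two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison. Where a gene was well above background on no array of a group, its change is given as a lower bound against the dimmest well-above-background signal of those arrays. Single genes named for their own sake (Rora and sex-linked genes) also had exact permutation tests of 4 arrays against 4. The 39 gene lists were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and limma fry served as alternatives, and list members were also adjusted over the list alone. Genes near Rora were counted within 20 Mb and tested with Fisher's exact test. The relation between the smoke and genotype effects was set beside 100 simulated data sets with shared WT smoke arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

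The comparisons, lists, tests and alternatives were fixed before the data were examined, except those said to be chosen later. Some sex-linked genes, genes near Rora and further list members are named outside the rule below and do not enter the totals over alternatives. The other named genes followed a fixed rule. In each comparison they were the 12 largest rises and 12 largest falls among genes that passed, whose 4 arrays did not overlap the other 4, that were well above background on all 4 arrays of the brighter group, and whose symbol was no clone or accession name. Rora and up to 4 members of each described list with the smallest p were added. Which lists are described was settled after their results were seen, and this choice sets which list members are named and enter the totals over alternatives; lists given by their test alone had no members added. Some genes that meet the rule are not reported here and are left out of the totals over alternatives and over single arrays; they stay in every count of genes and every list test. The fit was tested on simulated data of 19736 genes with the spread of these arrays: it recovered 70.1%, 88.1% and 98.5% of genes set to change 1.5, 2 and 4-fold between WT smoke and WT room air, and 71.6%, 89.6% and 98.5% between mutant and WT smoke. Genes set not to change made up 5.0% and 4.42% of the calls.

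Alternatives were normexp background correction (offset 50), quantile normalization, scaling on the median of bright probes, the authors' value table, no filter and a stricter filter on dim probes, all probes per gene, a variance trend with robust fitting, only the 8 arrays compared, array weights, replicate number, slide or scan as a block, and leaving out each array. Added after seeing the data were the omission of X- and Y-linked genes and of genes within 30 Mb of Rora, and normexp followed by quantile normalization. Leaving the 4 room-air arrays out of the genotype comparison is the planned setting of only the 8 arrays compared. Control spots and 4 probes with too many outlier spots were left out.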

Results

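Lung RNA of 12 mice was measured, 4 per group: wild type (WT) in room air, WT exposed to cigarette smoke, and Rora mutants exposed to smoke. Rora encodes a nuclear receptor that binds ROR elements in DNA and takes part in the circadian clock and in immune cell development. Of 41174 probes, 30191 were kept and stood for 19824 genes. The share of spots well above background ran from 70.1% (WT smoke replicate 4) to 74.8% (WT smoke replicate 2), and the 75th percentile of the signal from 785.2 to 1313 intensity units on the same 2 arrays. Arrays of the same group correlated at r = 0.9941 to 0.9967 across genes, and arrays of different groups at 0.9872 to 0.9949; genes are not independent replicates. The first 3 principal components held 33.0%, 14.2% and 10.3% of the variance.

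Sex-linked transcripts divided the 12 arrays, all labelled male. Xist, the RNA that silences an X chromosome in females, had a level of 4.04 ± 0.07 (SD, n = 4) in WT room air, -5.39 ± 2.09 in WT smoke and -4.61 ± 1.26 in mutant smoke. The Y-linked genes Ddx3y, Kdm5d and Uty were well above background on 0 of 4 room-air arrays and on 4 of 4 arrays of each smoke group. Ddx3y was at least 127.1-fold higher and Kdm5d at least 17.6-fold higher in WT smoke than in room air. Eif2s3y, also Y-linked, was well above background on 2 of the 4 room-air arrays, at -6.93 ± 1.57 against 1.45 ± 0.07 in WT smoke. X-linked genes that are expressed from both X chromosomes of females were higher in room air: Kdm5c at 2.00 ± 0.08 against 1.25 ± 0.07 in WT smoke and 1.33 ± 0.07 in mutant smoke, Kdm6a at -1.17 ± 0.07 against -1.91 ± 0.08 and -1.89 ± 0.11, and Ddx3x at 3.51 ± 0.12 against 3.14 ± 0.10 and 3.22 ± 0.09. Eif2s3x stood at 2.74 ± 0.07 in room air and 2.17 ± 0.05 in WT smoke by its brightest probe, while 1 of its other probes was lower in room air (-1.22 ± 0.15 against 1.39 ± 0.03). For Xist, Ddx3y, Kdm5d, Uty, Kdm5c, Kdm6a and Ddx3x, room air against WT smoke gave an exact permutation p of 0.0286 each, the smallest that 4 arrays against 4 allow. Sex-linked signal and exposure coincided on all 12 arrays, so both comparisons with room air hold this difference. The comparison of the 2 smoke groups does not.

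**Figure D1:**
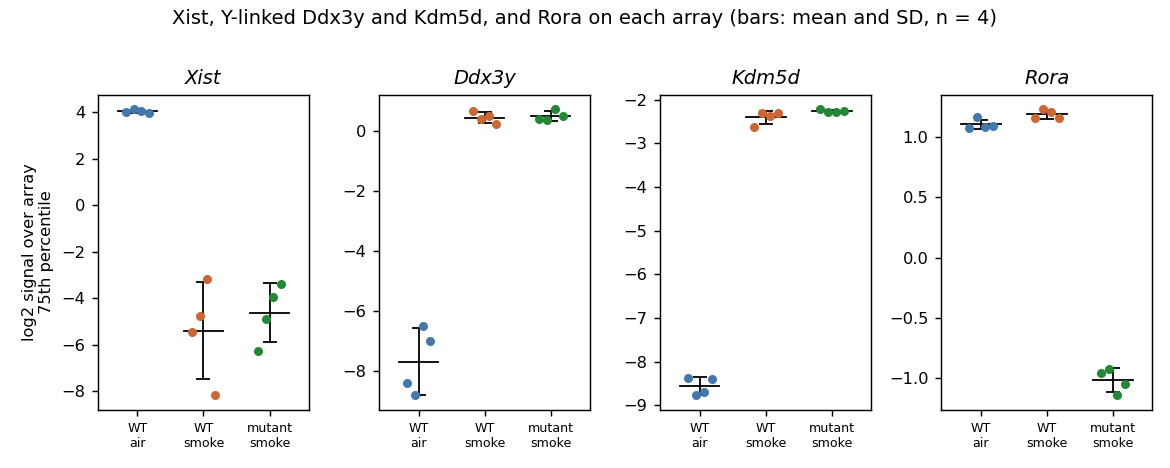
Level of Xist, Ddx3y, Kdm5d and Rora (log2 signal over the array's 75th percentile) on each of the 12 arrays, 1 panel per gene with its own axis, by group; lines and bars give the mean and SD of 4 arrays. The room-air arrays lie at a mean of 4.04 for Xist and -7.67 for Ddx3y, apart from all 8 smoke arrays, and the mutants lie at -1.01 for Rora, below all 8 WT arrays.

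Rora RNA was lower in the smoke-exposed mutants than in both WT groups. Its representative probe (chromosome 9, 69177968 to 69178027 on mm8) read 1.10 ± 0.04 (SD, n = 4) in WT room air, 1.18 ± 0.04 in WT smoke and -1.01 ± 0.10 in mutant smoke. The mutants fell by 2.20 ± 0.06 (SE) log2 units against WT smoke (limma adjusted p = 1.16e-09), on all 4 arrays. With the slide as a block the change was -2.18 (adjusted p = 7.63e-08), and within the 3 slides it was -2.11, -2.11 and -2.29. The other 2 kept probes gave -2.33 (69178068 to 69178127) and -2.34 (69184462 to 69184521), and each of the 3 had an exact permutation p of 0.0286. WT smoke and WT room air differed in Rora by 0.08 ± 0.06 log2 units (adjusted p = 0.478).

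The smoke exposure of WT mice was compared with room air to ask which lung genes went with smoke. Enzymes of xenobiotic metabolism and of the antioxidant response rose: Cyp1b1 24.1-fold, Cyp1a1 11.0-fold and Ahrr, a repressor of the aryl hydrocarbon receptor, by 4.32 ± 0.23 log2 units (SE), each on 4 of 4 arrays. Slc7a11, the cystine transporter that feeds glutathione synthesis, rose 7.16-fold and the quinone reductase Nqo1 5.06-fold. Genes of mucus-producing goblet cells fell, with log2 changes of -6.42 for Clca1, -2.52 for Agr2 and -2.00 for Tff2. Of 19824 genes, 457 were higher and 506 lower in smoke; 327 of them changed at least 1.5-fold. Groups did not overlap for 12.9% of genes, against 2.86% by chance. These 2 groups also differed in Xist by -9.43 log2 units, and 41 of 662 X-linked genes (6.19%) passed. The autosomes had shares of 1.84% (chromosome 18) to 6.37% (chromosome 15), so the X-linked share lay within their range. Of 6 Y-linked genes, 5 passed. Autosomal genes may differ with sex too, so these shares do not show how many of the calls go with sex.

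The 12 largest rises held 4 Y-linked genes (Eif2s3y, Ddx3y, Kdm5d, Uty), and beside those already named Artn (2.02 ± 0.18 log2 units, SE), a neurotrophic factor, the aldehyde dehydrogenase Aldh3a1 (1.89 ± 0.15) and the chemokine Ppbp (1.82 ± 0.17). The 12 largest falls held Xist and its antisense RNA Tsix (-1.85 ± 0.19), the nucleotidase Entpd8 (-2.89 ± 0.15, well above background on 3 of 4 smoke arrays), the antimicrobial protein lactoferrin, Ltf (-2.03 ± 0.37), Cldn22 (-1.88 ± 0.29), Gp2 (-1.86 ± 0.26) and the fibrinogen chain Fgg (-1.84 ± 0.19). Sult2a2 was at least 2.99-fold and Dnajc5b at least 2.46-fold lower.

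Among targets of the aryl hydrocarbon receptor, 5 of 6 measured members rose and 0 fell (6 rose adjusted over the list alone); the list median was 2.90 log2 units (camera adjusted p = 1.64e-17, and adjusted p = 0.0178 with an estimated correlation). Tiparp, the 1 member that did not pass, changed by 0.15. With the slide as a block the list gave a median of 2.86 and an adjusted p of 1.23e-15 (adjusted p = 0.056 with an estimated correlation), and within slides medians of 3.27, 2.53 and 2.95. Of 35 NRF2 antioxidant and glutathione genes, 24 rose, 0 fell and 11 did not pass (29 rose adjusted over the list alone), with a median of 0.48 (adjusted p = 6.09e-37, and adjusted p = 7.99e-03 with an estimated correlation). The carbonyl reductase Cbr3 rose by 1.76 ± 0.08, the carboxylesterase Ces1g by 1.78 ± 0.09 and the aldo-keto reductase Akr1b8 by 0.96 ± 0.07. The slide block gave a median of 0.44 (adjusted p = 8.03e-34, and adjusted p = 0.0374 with an estimated correlation), and the slides 0.58, 0.37 and 0.45. Nqo1 is in both lists. Of 46 genes of p53 and DNA damage, 4 rose and 0 fell (5 rose adjusted over the list alone): Gdf15 (1.44), Gadd45g (0.57), Plk3 (0.50) and Psrc1 (0.25), the last lost in 18 of 27 settings. The list passed (median 0.07, adjusted p = 1.06e-03, and adjusted p = 0.0381 with an estimated correlation); with the slide as a block its median was 0.07 and its adjusted p 1.36e-03 (adjusted p = 0.0844 with an estimated correlation), and within slides the medians were 0.02, 0.05 and 0.13.

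Of 15 goblet cell and mucin genes, 11 fell and 0 rose (12 fell adjusted over the list alone). The gel-forming mucins Muc5b (-1.63 ± 0.10) and Muc5ac (-1.42 ± 0.16; its other probe -0.12) fell, beside Agr2, Clca1, Tff2 and Gp2. The list median was -0.92 (adjusted p = 5.39e-14), but adjusted p = 0.052 with an estimated correlation; the slide block gave -0.88 (adjusted p = 1.36e-12) and the slides -0.69, -0.80 and -1.37. Of 28 genes of cholesterol and fatty acid synthesis, 7 fell and 0 rose (14 fell and 1 rose adjusted over the list alone), among them Fdps (-0.40; its other probe -0.12) and Cyp51 (-0.35); the median was -0.19 (adjusted p = 4.54e-09, and adjusted p = 0.0745 with an estimated correlation). The slide block gave -0.17 (adjusted p = 1.02e-08), and the slides -0.19, -0.21 and -0.15. Of 37 cell cycle genes, 8 fell and 0 rose (17 fell adjusted over the list alone), such as the kinesin Kif2c (-0.81) and the checkpoint kinase Bub1 (-0.54). The call of Bub1 ended with the slide as a block and in 11 of 27 settings, and that of Kif2c in 5 of 26. The list passed (median -0.31, adjusted p = 5.42e-11), but adjusted p = 0.324 with an estimated correlation; the slide block gave -0.31 (adjusted p = 3.06e-11) and the slides -0.51, -0.04 and -0.52. Of 20 markers of alveolar type 2 cells, which make surfactant, 6 fell and 0 rose (8 fell adjusted over the list alone), such as Muc1 (-0.33), Lamp3 (-0.27) and the surfactant protein Sftpd (-0.45); the median was -0.14 (adjusted p = 3.79e-04, and adjusted p = 0.283 with an estimated correlation). The slide block gave -0.14 (adjusted p = 1.36e-03), and the slides -0.19, -0.20 and -0.09. The calls of Sftpd and Lamp3 ended in 8 and 3 of 27 settings. Muc1 is in the type 2 and the goblet list. Alveolar type 1 markers were higher (1 of 16 passed, median 0.14, adjusted p = 9.03e-05) and ciliated markers lower (1 of 28, -0.18, adjusted p = 3.97e-05). Cardiac muscle genes (2 of 18, -0.23, adjusted p = 9.61e-04) and skeletal muscle genes (1 of 15, -0.21, adjusted p = 0.0163) were lower too. With an estimated correlation these 4 had adjusted p of 0.283, 0.462, 0.613 and 0.283, and with the slide as a block 5.44e-04, 2.10e-04, 0.0104 and 0.0229. Within slides the medians were 0.04, 0.15 and 0.15 for type 1 and 0.04, -0.31 and -0.27 for ciliated lists. They were -0.18, -0.28 and 0.08 for cardiac and -0.16, -0.17 and -0.07 for skeletal muscle lists. Ciliated and cardiac lists thus turned on 1 slide. Each slide value rests on a single array of at least 1 of the 2 groups, so a turn can come from 1 mouse. Lists of T cells (median -0.21), dendritic cells (-0.10) and smooth muscle (-0.16) also passed as lower and type 17 genes (0.11) as higher. The 3 lower lists each turned on 1 slide, with medians there of 0.09, 0.09 and 0.02. The adjusted p of these 4 lists were 9.56e-03, 0.017, 0.017 and 9.75e-03, and 0.748, 0.712, 0.613 and 0.172 with an estimated correlation. Erythroid genes passed as higher (2 of 13 rose, median 0.18, adjusted p = 0.0233, and adjusted p = 0.668 with an estimated correlation). Beside each of these lists, Xist was 4.04 on average in room air and -5.39 in smoke.

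Of 35 genes of smoke-associated alveolar macrophages, 8 rose and 2 fell (12 and 3 adjusted over the list alone), led by Gpnmb (0.94 ± 0.11), Mcoln3 (0.58) and Pparg (0.42), while the anion transporter Slc26a4 fell by 0.92; it is also in the goblet list. The list median was 0.07 (adjusted p = 2.26e-03, and adjusted p = 0.462 with an estimated correlation), with the slide block 0.09 (adjusted p = 5.27e-03) and within slides 0.16, 0.05 and 0.07. Of 17 glucocorticoid-responsive genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone): the metallothioneins Mt2 (1.31 ± 0.09) and Mt1 (0.70 ± 0.09; its other probe 2.06), Sgk1 (0.37), and Lcn2, which fell by 0.64. The median was 0.21 (adjusted p = 9.61e-04, and adjusted p = 0.462 with an estimated correlation), with the slide block 0.20 (adjusted p = 3.73e-03) and within slides 0.05, 0.02 and 0.55; Sgk1 lost its call in 19 and Lcn2 in 18 of 27 settings. Of 23 circadian clock genes, 0 passed in limma and 4 had an unadjusted p under 0.05; the list did not pass (median 0.03, adjusted p = 0.422). In this comparison 18 of the 39 lists passed, 3 with an estimated correlation, and 7 of the 35 ways to divide the 8 arrays 4 and 4 gave as many. With the slide as a block 350 genes were higher and 335 lower, 629 of them among the 963, and without X- and Y-linked genes 436 were higher and 473 lower; a normexp background correction left 40 and 13 and ended the call of the alveolar type 2 list (adjusted p = 0.111). Lower genes numbered 323, 298, 334 and 279 without WT room air replicates 1 to 4 and 264, 308 and 302 without WT smoke replicates 2 to 4, and higher genes 275 without WT room air replicate 4 and 299 without WT smoke replicate 3.

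**Figure D2:**
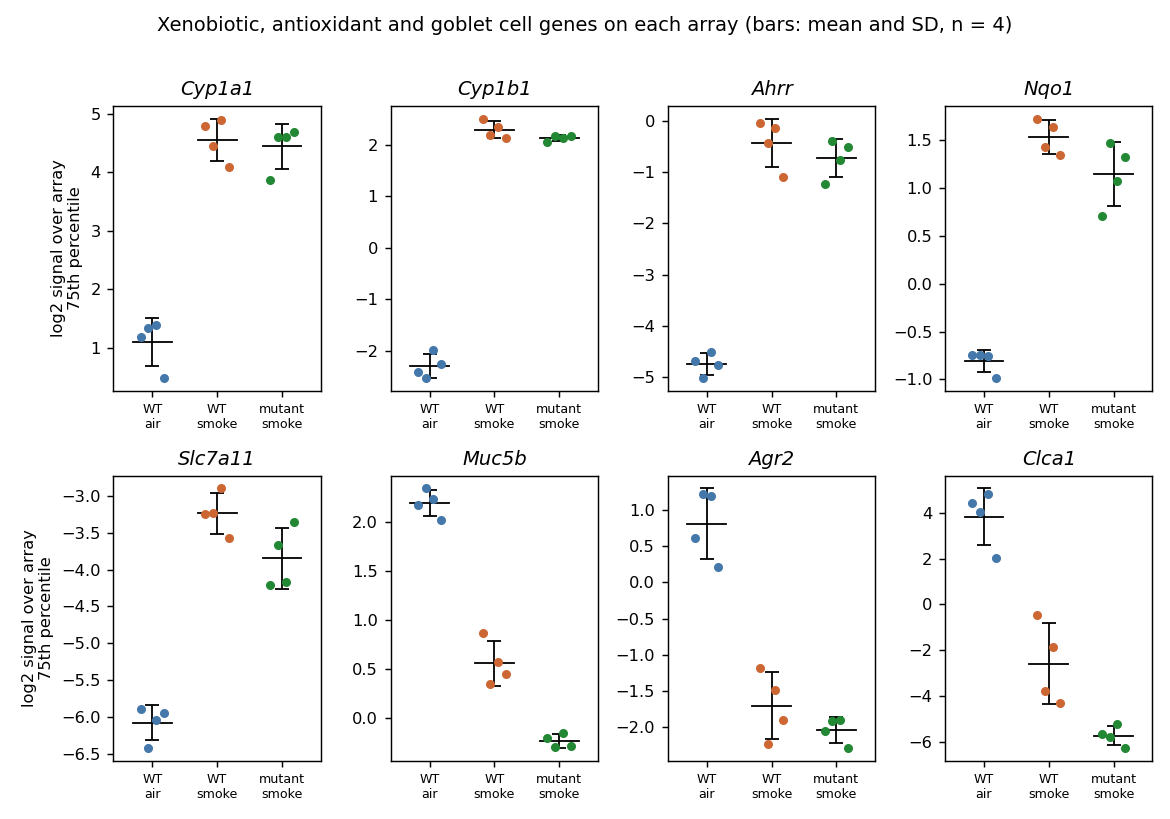
Level of 8 genes (log2 signal over the array's 75th percentile) on each array, 1 panel per gene with its own axis, by group; lines and bars give the mean and SD of 4 arrays. Cyp1b1 lies at a mean of -2.30 in WT room air, 2.29 in WT smoke and 2.13 in mutant smoke, and Muc5b at 2.19, 0.56 and -0.23.

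Mutant and WT mice, both in smoke, were compared to ask which genes went with the Rora genotype under smoke. Genes of the alveolar macrophage list rose in part: 15 of 35 passed as higher in the mutants, such as the lectin Siglecf (0.82 ± 0.08 log2 units, SE). Slc26a4, which is in this list and in the goblet list, rose 4.18-fold. The macrophage list did not pass in camera with an estimated correlation (adjusted p = 0.0723). Clock output genes fell, led by the transcription factors Hlf (-1.24 ± 0.08) and Dbp (-0.92 ± 0.09). Receptors of type 2 immunity fell, the IL-33 receptor Il1rl1 (-1.05 ± 0.07) and the IL-25 receptor Il17rb (-1.08 ± 0.13). Fkbp5, a glucocorticoid-induced chaperone, rose 3.14-fold by its brightest probe, while its 2 other probes rose by only 0.39 and 0.44 log2 units. Of 19824 genes, 492 were higher and 706 lower in the mutants; 392 of them changed at least 1.5-fold, and groups did not overlap for 13.4% of genes against 2.86% by chance.

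The 12 largest rises also held Cd163l1 (1.35 ± 0.17), the fat hormone resistin, Retn (1.49 ± 0.36), Ace3 (1.44 ± 0.11) and Fgg (1.41 ± 0.19). Tmem45b (1.77 ± 0.40), Lrrc15 (1.43 ± 0.34) and Lctl (2.33 ± 0.43) were among them too. Kininogen, Kng1, was at least 2.81-fold, Acvr1c at least 1.96-fold and Klb at least 1.76-fold higher. The 12 largest falls held Clca1 (-3.13 ± 0.79), Ooep (-2.97 ± 0.24), Lrmda (-2.80 ± 0.05), Ntm (-2.22 ± 0.37), Rora, Zfp663 (-1.75 ± 0.23), Lingo1 (-1.68 ± 0.18), Gp2 (-1.61 ± 0.26), the immediate early factor Egr3 (-1.38 ± 0.23), Leo1 (-1.34 ± 0.13), Wfdc12 (-1.31 ± 0.16) and Cpxm1 (-1.25 ± 0.18). Lctl and Lrrc15 were well above background on 1 of 4 WT smoke arrays, and Ntm and Lingo1 on 1 and Zfp663 on 3 of 4 mutant arrays, so these sizes rest in part on signal near background. Lctl, Ooep, Lingo1 and Leo1 lie within 20 Mb of Rora. The calls of Fkbp5 ended without Rora mutant smoke replicate 4 or without WT smoke replicate 1, and that of Clca1 ended in 13 of 28 settings. The slide block ended the calls of Retn, Tmem45b and Acvr1c. Over all settings they ended in 9 of 28, 8 of 28 and 8 of 27, and that of Lrrc15 in 9 of 27.

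Of 23 circadian clock genes, 9 fell, 2 rose and 12 did not pass (11 and 3 adjusted over the list alone). Beside Hlf and Dbp, the repressors Bhlhe40 (-0.50 ± 0.07) and Bhlhe41 (-0.86 ± 0.11) fell. Genes of the same list that rose were Clock (0.35) and Nfil3 (0.33), and Nr1d1, the nuclear receptor that competes for ROR elements, fell by 0.98 (its other probes -0.38 and -0.85). The list median was -0.18 (adjusted p = 5.17e-04), but adjusted p = 0.0723 with an estimated correlation; with the slide as a block it was -0.19 (adjusted p = 6.79e-04) and within slides -0.25, -0.14 and -0.22. Of 24 reported ROR-alpha targets, 4 fell and 2 rose (5 and 3 adjusted over the list alone). Rora itself, Nr1d1, Cyp7b1 (-0.36) and Shh (-0.31) fell, and Cidec (0.50) and Cd36 (0.27) rose. The list did not pass in camera (median 0.00, adjusted p = 0.956). In fry it passed as lower (adjusted p = 1.3e-03). The list holds Rora, the mutated gene, so the fall of Rora itself enters the counts and both tests. The call of Cidec ended with the slide as a block and in 10 of 28 settings, and that of Cd36 in 7.

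Of 18 genes of type 2 immunity and innate lymphoid cells, 4 fell and 0 rose (6 fell adjusted over the list alone): Il1rl1, Il17rb, Arg1 (-1.05 ± 0.22) and the leukotriene receptor Cysltr1 (-0.58 ± 0.12; its other probe -0.24). The call of Arg1 ended in 3 of 28 settings, among them normexp, where its sign turned, and the omission of WT smoke replicate 1. The sign of Il17rb turned with normexp too (0.32, and 0.22 with the median change of all genes taken off). Arg1 did not turn with that median taken off. The median was -0.27 (adjusted p = 9.78e-04), but adjusted p = 0.0723 with an estimated correlation; the slide block gave -0.25 (adjusted p = 1.17e-03) and the slides -0.32, -0.19 and -0.18. A normexp background correction turned the direction of this list, with adjusted p = 0.915. Of 13 eosinophil and mast cell markers, 5 rose and 1 fell, the same counts as adjusted over the list alone: Siglecf and the mast cell proteases Cpa3 (1.22 ± 0.17), Mcpt4 (0.98), Cma1 (0.75) and Tpsb2 (0.78) rose, and Gata1 fell by 0.69. The median was 0.15 (adjusted p = 3.01e-03, and adjusted p = 0.0723 with an estimated correlation), with the slide block 0.14 (adjusted p = 1.63e-03) and within slides 0.30, 0.31 and 0.57. Of 35 smoke-associated alveolar macrophage genes, 15 rose and 0 fell (21 rose adjusted over the list alone): beside Slc26a4 and Siglecf, F7 (0.74 ± 0.07) and the chemokine Ccl6 (0.50 ± 0.08). The median was 0.38 (adjusted p = 2.28e-16), but adjusted p = 0.0723 with an estimated correlation; the slide block gave 0.38 (adjusted p = 9.78e-16) and the slides 0.38, 0.33 and 0.30. Siglecf is in both lists, and Slc26a4 is also in the goblet list.

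Of 39 genes of extracellular matrix and elastic fibres, 8 rose and 3 fell (13 and 5 adjusted over the list alone), among them Mfap4 (0.90 ± 0.12), tenascin C, Tnc (1.03 ± 0.15), and fibulin 1, Fbln1 (0.78 ± 0.12), while Ccn2 fell by 0.60. The median was 0.19 (adjusted p = 2.43e-03, and adjusted p = 0.593 with an estimated correlation), with the slide block 0.25 (adjusted p = 3.21e-04) and within slides 0.17, 0.37 and 0.04; the call ended without Rora mutant smoke replicate 2 (adjusted p = 0.102). Of 17 glucocorticoid-responsive genes, 3 rose and 0 fell (4 rose adjusted over the list alone): Fkbp5, Pdk4 (0.98 ± 0.17) and Cdkn1a (0.47 ± 0.08). The median was 0.32 (adjusted p = 4.10e-04, and adjusted p = 0.38 with an estimated correlation), with the slide block 0.31 (adjusted p = 7.06e-04) and within slides 0.28, 0.37 and 0.15. Of 35 NRF2 genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone), such as Gsta3 (-0.48), Gpx2 (-0.46) and Gclc (-0.94), the last within 20 Mb of Rora. The median was -0.15 (adjusted p = 1.68e-04, and adjusted p = 0.358 with an estimated correlation), with the slide block -0.15 (adjusted p = 1.49e-04) and within slides -0.20, -0.03 and -0.21. Of 28 genes of cholesterol and fatty acid synthesis, 7 fell and 1 rose (10 and 1 adjusted over the list alone), such as Sqle (-0.36), whose call ended in 3 of 28 settings. The median was -0.14 (adjusted p = 1.08e-03, and adjusted p = 0.358 with an estimated correlation), with the slide block -0.13 (adjusted p = 7.06e-04) and within slides -0.09, -0.13 and -0.13.

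Airway epithelial lists were lower in the mutants. Of 28 ciliated cell markers, 4 fell and 0 rose (11 fell adjusted over the list alone), such as Lrriq1 (-0.64) and Spag17 (-0.47), with a median of -0.19 (adjusted p = 8.46e-07, and adjusted p = 0.38 with an estimated correlation), -0.22 with the slide block (adjusted p = 3.91e-08) and -0.43, -0.11 and -0.19 within slides. Of 19 club cell markers, 4 fell and 0 rose, the same count as adjusted over the list alone, such as Fmo2 (-0.55; its other probes -0.20 and -0.26) and Gabrp (-0.62); the median was -0.19 (adjusted p = 9.78e-04, and adjusted p = 0.382 with an estimated correlation), -0.21 with the slide block (adjusted p = 1.15e-03) and -0.23, -0.07 and -0.31 within slides. Of 15 goblet cell and mucin genes, Muc5b (-0.79), Gp2, Tff2 (-1.11) and Clca1 fell and Slc26a4 rose (5 fell and 1 rose adjusted over the list alone); the median was -0.25 (adjusted p = 0.0324, and adjusted p = 0.593 with an estimated correlation), -0.31 with the slide block (adjusted p = 0.0182) and -0.31, -0.13 and -0.57 within slides. The calls of Spag17, Lrriq1, Gabrp and Tff2 ended in 6, 3, 5 and 4 of 28 settings, and the sign of Lrriq1 turned with normexp. Markers of tissues beside the lung differed between the 2 smoke groups as well. Of 18 cardiac muscle genes, 4 rose and 0 fell (11 rose adjusted over the list alone), such as Pln (0.80) and Myl3 (1.06), with a median of 0.37 (adjusted p = 8.46e-07, and adjusted p = 0.38 with an estimated correlation), 0.35 with the slide block (adjusted p = 1.13e-06) and 0.21, 0.47 and 0.28 within slides. Of 15 skeletal muscle genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone), such as Myh1 (0.88, well above background on 1 of 4 WT smoke arrays; its call ended with the slide as a block and in 9 of 27 settings), with a median of 0.38 (adjusted p = 1.68e-04, and adjusted p = 0.0723 with an estimated correlation), 0.38 with the slide block (adjusted p = 1.59e-04) and 0.25, 0.29 and 0.28 within slides. The 2 muscle lists were lower in WT smoke than in room air (-0.23 and -0.21). Mutant smoke against room air gave camera medians of 0.13 (adjusted p = 0.125) and 0.14 (adjusted p = 0.288). With the slide as a block the cardiac list passed (0.18, adjusted p = 0.0336, but adjusted p = 0.681 with an estimated correlation). The skeletal list did not (0.12, adjusted p = 0.236). The cardiac call thus depends on the block, and the data do not show whether the difference lies in the mutants or in the WT smoke arrays. Of 15 adipose genes, 4 rose and 0 fell (5 rose adjusted over the list alone), namely Lipe (0.50; its other probes 0.57 and -0.02), Fabp4 (1.02), Cidec and Retn, with a median of 0.50 (adjusted p = 2.18e-06, and adjusted p = 0.337 with an estimated correlation), 0.48 with the slide block (adjusted p = 3.17e-05) and 0.50, 0.67 and 0.28 within slides. The slide block ended the calls of Fabp4, Cidec and Retn. They ended in 10, 10 and 9 of 28 settings. Fabp4 and Cidec are also in the macrophage list. In this comparison 22 of the 39 lists passed. Among those not yet named, alveolar type 2 (0.15, adjusted p = 4.10e-04), erythroid (0.56, adjusted p = 7.30e-03), cell cycle (0.10, adjusted p = 1.23e-03) and endothelial lists (0.07, adjusted p = 0.0378) were higher by their test, with 1, 0, 1 and 0 members risen and 0, 0, 0 and 1 fallen. Interferon-stimulated (-0.18, adjusted p = 3.58e-03) and dendritic cell lists (-0.16, adjusted p = 0.0428) were lower by theirs, with 0 and 1 members risen and 1 and 0 fallen. The dendritic list did not pass with the slide as a block (adjusted p = 0.12). Medians turned on 1 slide for endothelial (-0.02), erythroid (-0.02) and interferon-stimulated lists (0.16). With an estimated correlation camera passed 0, and 6 had an unadjusted p under 0.05; fry passed 13. With the slide as a block 381 genes were higher and 499 lower, 797 of them among the 1198, and without the room-air arrays 335 and 410. Leaving out Rora mutant smoke replicate 4 left 281 higher and 298 lower genes and 261 of at least 1.5-fold, leaving out WT smoke replicate 1 left 295 and 332, replicate 2 left 325 higher, and replicate 3 left 312 and 390; normexp left 12 higher and 16 lower.

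**Figure D3:**
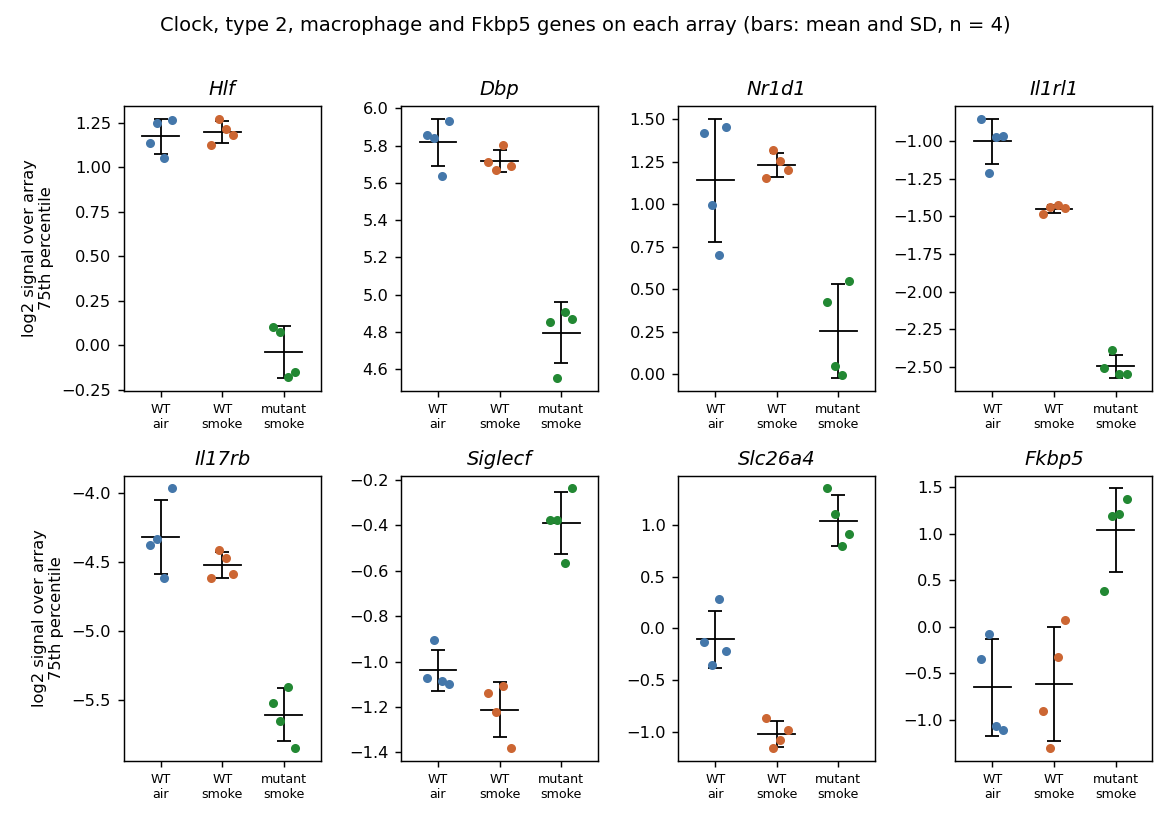
Level of 8 genes (log2 signal over the array's 75th percentile) on each array, 1 panel per gene with its own axis, by group; lines and bars give the mean and SD of 4 arrays. Slc26a4 lies at a mean of -1.02 in WT smoke and 1.04 in mutant smoke, and Fkbp5 at -0.61 and 1.04 with SDs of 0.61 and 0.45.

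Genes that differed between mutant and WT under smoke lay near Rora more often than elsewhere. Within 20 Mb of Rora on chromosome 9 (49177998 to 89177998 on mm8), 50 of 365 genes (13.7%) passed, against 1139 of 19302 (5.90%) elsewhere, an odds ratio of 2.53 (95% interval 1.83 to 3.44, Fisher's exact p = 8.34e-08). Of these 50 genes, 25 were higher and 25 lower in the mutants, and among them Il18 rose by 0.42 and Ooep fell by 2.97 log2 units. Some of the 50 lie side by side, such as NAP033385-1 with Col12a1 and AK083178 with Mns1. Fisher's test takes them as independent, so the interval may be too narrow. In the comparison of smoke with room air, 23 of the same 365 genes passed (odds ratio 1.33, 0.825 to 2.04, Fisher's exact p = 0.217). Without genes within 30 Mb of Rora, a setting added after seeing the data, 452 genes were higher and 655 lower in the mutants. With normexp the odds ratio was 4.43 (Fisher's exact p = 0.0834). Each omission of 1 array gave a higher odds ratio than 2.53, from 2.603 to 3.97, with 3.97 without WT smoke replicate 1 and 3.95 without Rora mutant smoke replicate 4.

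**Figure D4:**
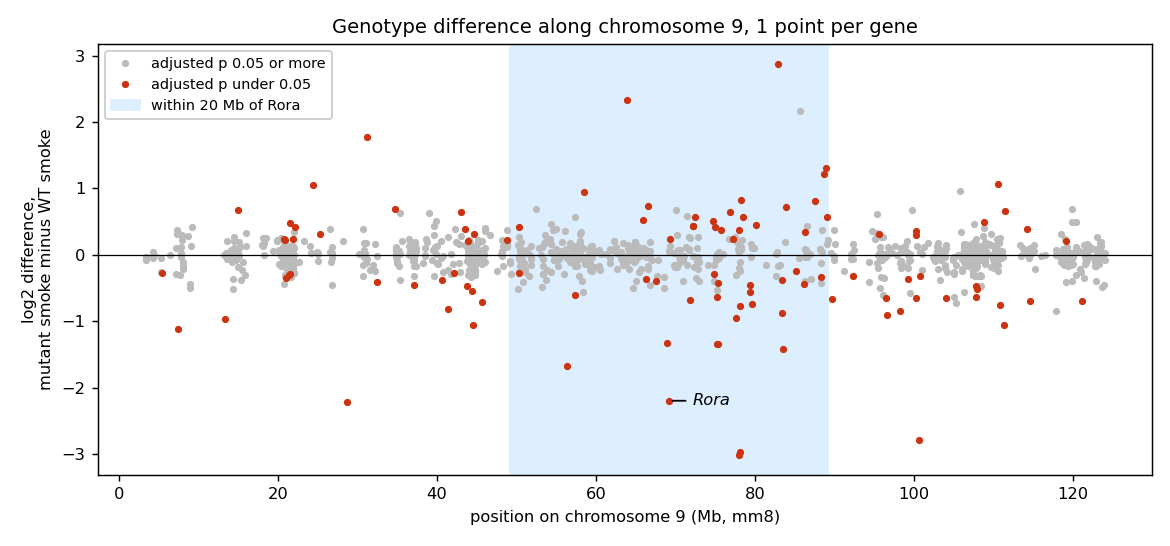
Log2 difference of mutant smoke minus WT smoke for each gene with a probe on chromosome 9, by position in Mb on mm8; red points passed at an adjusted p under 0.05 and the blue band covers 20 Mb on either side of Rora. Of the 365 genes in the band other than Rora, 50 passed, 25 upward and 25 downward.

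Smoke-exposed mutants were set against WT in room air, where exposure, genotype and sex-linked signal all differ. Xenobiotic and antioxidant genes were higher: Cyp1b1 21.5-fold, Ahrr 16.3-fold, Cyp1a1 10.2-fold and Slc7a11 4.69-fold. The lipid regulator Angptl4 rose 5.81-fold. Goblet cell genes fell, with log2 changes (± SE) of -9.55 ± 0.79 for Clca1, -3.47 ± 0.26 for Gp2, -3.11 ± 0.23 for Tff2, -2.85 ± 0.25 for Agr2 and -2.42 ± 0.10 for Muc5b. Of 19824 genes, 1322 were higher and 1990 lower; 912 changed at least 1.5-fold, and groups did not overlap for 21.0% against 2.86% by chance. Xist fell by 8.65 log2 units, and 110 of 662 X-linked genes (16.6%) passed. Shares on the autosomes ran from 14.3% (chromosome 19) to 19.8% (chromosome 9), so the X-linked share lay within their range. Of 6 Y-linked genes, 5 passed. Here too the shares do not show how many of the calls go with sex.

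Other large rises were the Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty; Lrrc15 was at least 2.51-fold and Kng1 at least 2.68-fold higher. Other large falls were Tsix (-2.56), Ooep (-2.93), Entpd8 (-2.75) and Lrmda (-2.70), and Igkv8-16 was at least 5.70-fold and Slc38a11 at least 4.21-fold lower. Of 35 smoke-associated alveolar macrophage genes, 25 rose and 0 fell, the same counts as adjusted over the list alone (median 0.52, adjusted p = 3.23e-16, and adjusted p = 0.0401 with an estimated correlation), among them Ccl6 (0.96), Gpnmb (1.35) and Mcoln3 (1.08). Of 6 aryl hydrocarbon receptor targets, 6 rose, as adjusted over the list alone (median 2.65, adjusted p = 1.38e-11, and adjusted p = 0.0401 with an estimated correlation). Of 35 NRF2 genes, 22 rose and 1 fell (23 and 1 adjusted over the list alone; median 0.38, adjusted p = 2.38e-15, and adjusted p = 0.0401 with an estimated correlation), such as Cbr3 (1.42) and Ces1g (1.44). Of 46 genes of p53 and DNA damage, 12 rose and 0 fell (13 rose adjusted over the list alone; median 0.07, adjusted p = 2.38e-04, and adjusted p = 0.0401 with an estimated correlation), such as Gdf15 (1.75), Gadd45g (0.93) and the cell cycle inhibitor Cdkn1a (0.70). Of 28 genes of cholesterol and fatty acid synthesis, 18 fell and 1 rose (19 and 1 adjusted over the list alone; median -0.32, adjusted p = 1.05e-10, and adjusted p = 0.0463 with an estimated correlation), such as Idi1 (-0.55). With the slide as a block the medians of these 5 lists were 0.55, 2.56, 0.38, 0.07 and -0.30, and each had adjusted p = 0.084 with an estimated correlation; within slides they were 0.56, 0.51 and 0.37 for macrophage genes, 2.31, 2.74 and 2.61 for receptor targets, 0.37, 0.39 and 0.31 for NRF2 genes, 0.06, 0.10 and 0.10 for p53 genes, and -0.34, -0.34 and -0.31 for cholesterol genes.

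Of 28 ciliated cell markers, 18 fell and 0 rose (24 fell adjusted over the list alone), such as Spag17 (-0.72) and Drc1 (-0.50), with a median of -0.36 (adjusted p = 6.12e-11, and adjusted p = 0.16 with an estimated correlation), -0.39 with the slide block (adjusted p = 3.43e-11) and -0.34, -0.43 and -0.43 within slides. Of 15 goblet cell and mucin genes, 11 fell and 2 rose, as adjusted over the list alone, with a median of -1.53 (adjusted p = 3.22e-08, and adjusted p = 0.117 with an estimated correlation), -1.66 with the slide block (adjusted p = 8.75e-08) and -0.70, -1.59 and -2.02 within slides. Of 17 glucocorticoid-responsive genes, 9 rose and 0 fell (10 rose adjusted over the list alone), such as Mt2 (1.10) and Pdk4 (1.44), with a median of 0.50 (adjusted p = 3.22e-08, and adjusted p = 0.136 with an estimated correlation), 0.47 with the slide block (adjusted p = 3.06e-07) and 0.39, 0.61 and 0.57 within slides. In this comparison 22 lists passed, 5 with an estimated correlation, and 2 of the 35 ways to divide the 8 arrays gave as many. With the slide as a block 1171 genes were higher and 1753 lower, and without X- and Y-linked genes 1272 and 1926. Without Rora mutant smoke replicate 4, 881 genes were higher, and scaling on the median of bright probes gave 1745 higher and 1709 lower.

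Whether the mutants differed from WT smoke in the direction opposite to smoke was asked across genes. The log2 changes of the 2 comparisons correlated at r = -0.136 with a covariance of -9.58e-03, and genes are not independent replicates. The comparison of WT smoke with room air also holds the difference in sex-linked signal. Its direction, and the genes that passed in it, are thus not those of smoke alone. Both comparisons use the WT smoke arrays; simulated smoke effects without a genotype effect gave a median r of -0.272 (-0.42 to 0.0284) and covariance of -0.0144. Of the 963 genes that passed for smoke, 64.1% went the opposite way in the mutants, against 68.0% (43.9 to 80.4) in that simulation, which called a median of 1823.5 genes for smoke, so the 2 shares come from sets of unequal size. Among genes that passed in both, 60 moved the same way and 124 the opposite way. Independent lists would share 11.3 genes higher in both, 18 lower in both, 16.3 higher then lower and 12.6 lower then higher. The data gave 23, 37, 62 and 62. The shared WT smoke arrays alone push genes to opposite signs, so independent lists are not the value without a genotype effect. With the WT smoke arrays divided 2 and 2 between the comparisons, r was 4.23e-03 (-0.0261 to 0.0505) and 59.2% (48.5 to 63.6) went the opposite way. Of the genes that then passed in both, 9 moved the same way and 15 the opposite way.

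**Figure D5:**
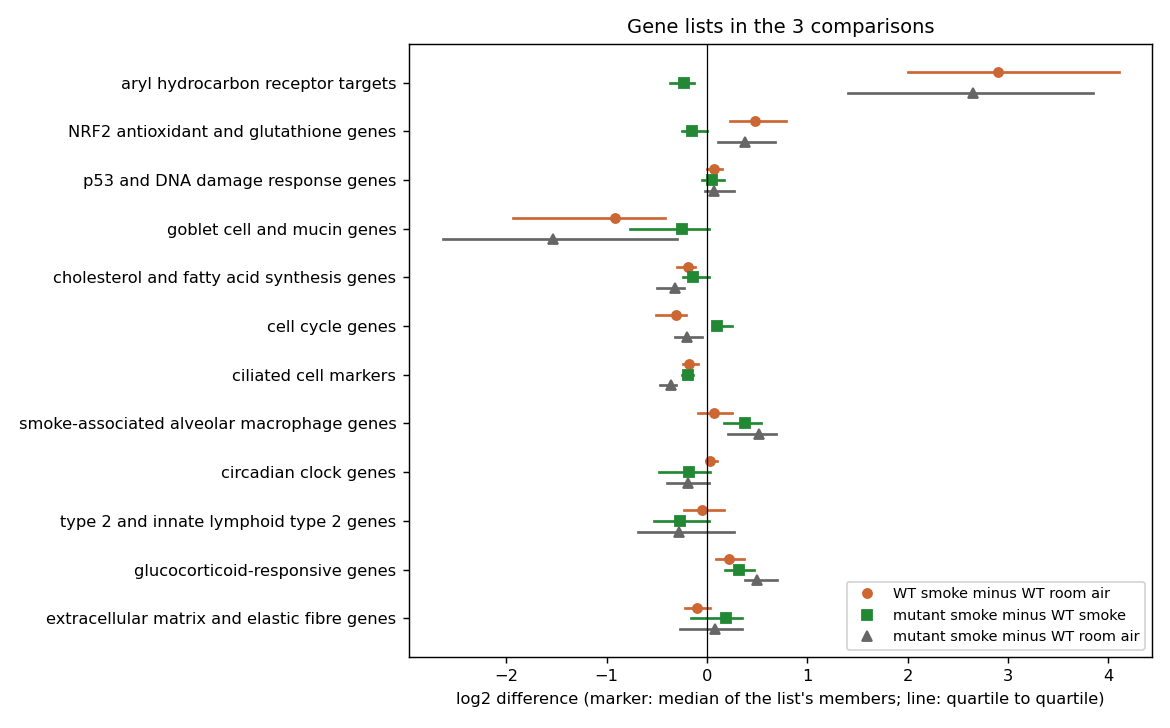
Median log2 difference of 12 gene lists in the 3 comparisons; markers give the median over a list's measured members and lines run from the lower to the upper quartile. Aryl hydrocarbon receptor targets lie at 2.90 for smoke in WT and 2.65 for mutant smoke against room air, and smoke-associated macrophage genes at 0.07, 0.38 and 0.52 in the order of the legend.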

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

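The tests of sex-linked transcripts, of genes near Rora by distance and probe, and of clock genes below were chosen after the results they test were seen; the search for single arrays far from the others was planned.

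Room-air arrays labelled male carried high Xist and no well-above-background signal of Ddx3y, Kdm5d and Uty. On 4 of 4 room-air arrays Xist and the representative probes of Kdm5c, Kdm6a, Ddx3x and Eif2s3x also lay above every smoke array, which is consistent with a mislabelled sex, that is, with room-air RNA from female mice. A mixture of male and female RNA is argued against by Ddx3y, whose mean level on the room-air arrays is at most 0.773% of the mean of the smoke arrays; Eif2s3y lies at 0.0834% to 0.774%. An exchange of room-air and smoke arrays is argued against because 0 room-air arrays lie within the range of the smoke arrays for Cyp1a1, Cyp1b1 or Ahrr. Sex-linked signal and exposure coincide on all 12 arrays, so from these arrays alone they cannot be separated for any gene in the comparisons with room air. A biological effect of sex stays open.

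Genes that passed between mutant and WT smoke lay near Rora more often than elsewhere. From 2 to 30 Mb away, beyond its neighbours, 65 of 520 genes passed, an odds ratio of 2.31 (1.74 to 3.02) against other chromosomes, where smoke against room air gave 1.20 (0.796 to 1.75); beyond 30 Mb on the same chromosome the odds ratio was 1.21 (0.84 to 1.69). This may reflect a strain variant, DNA around Rora carried over from another strain, and argues against local regulation by Rora within 2 Mb as the whole source, for which the same 2.31 is the deciding value. Of the 50 genes within 20 Mb, 50% were lower in the mutants (35.5% to 64.5%). Probe mismatch lowers signal, so it does not account for a rise of the representative probe. Other probes of the genes that rose fell for Rfx7 (-2.77 and -0.36), Lrrc1 (-0.35 and -0.27) and Bmp5 (-0.04). They rose for Bckdhb (0.79), Mlip (0.74), Myo5a (0.34) and Cd109 (0.18), and were mixed for Myo6 (-0.38 and 0.46). Some of the rises thus rest on the representative probe alone. For the genes that fell, probe mismatch cannot be told apart. There 8 other probes of 6 such genes had a median of -0.212, from -1.04 to 0.356, against -0.449 for the probes that passed.

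Clock output genes were lower in the smoke-exposed mutants: 8 of 12 fell and 0 rose (median -0.483 log2 units). Clock genes with ROR elements, which peak about opposite in the day, were to decide between a collection time that differed between the genotypes and lower activation through ROR elements. Of the 5 measured, 2 passed as higher and 0 as lower, with a median of 0.21 log2 units (-0.0556 to 0.355), so neither most passed as higher nor most as lower. The median lay above 0, but Nr1d1, which competes for ROR elements and is not among these 5, fell in the mutants. A rise of the 5 could follow from that fall, so the sign of the median does not count against lower activation. Collection time and lower activation cannot be told apart here, since few members were measured, 3 of the 5 did not pass, and the labels give no time of collection. A direct effect of the genotype on the output genes stays open as a biological explanation and was not tested.

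Single arrays stood far from the other 3 of their group in 29 of 573 groups of 4, where chance gives about 28.6. On the first principal component Rora mutant smoke replicate 4 lay at 32.2 (median of the others 20.4), and on the third WT smoke replicate 1 at 12.2. Mean levels of lists stood apart for cell cycle genes in WT room air replicate 2 (-1.60), clock genes in WT smoke replicate 3 (0.60), skeletal muscle genes in WT smoke replicate 2 (-1.73) and type 17 genes in mutant smoke replicate 3 (-0.59). In WT room air, single levels were Cysltr1 at -2.12 in replicate 1, Rora at 1.16, Pparg at 0.60 and Siglecf at -0.90 in replicate 2, and Nqo1 at -0.98, Ccl6 at 3.46 and Lrriq1 at -4.18 in replicate 4. In WT smoke they were Arg1 at -3.19, Gadd45b at 2.47 and Bub1b at -2.99 in replicate 1, and Ooep at -2.28 and Myh2 at -7.30 in replicate 4. In mutant smoke they were Cyp1a1 at 3.88 and Muc1 at -0.073 in replicate 1, Ooep at -4.45, Il17re at 1.95, Dbp at 4.55 and Lamp3 at 4.29 in replicate 2, Pparg at 0.84, F7 at 0.69, Il18 at 0.35 and Lat at -0.62 in replicate 3, and Igkv8-16 at -8.88 in replicate 4.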

How the results depend on the processing

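Normexp followed by quantile normalization and omitting X- and Y-linked genes or genes within 30 Mb of Rora were chosen after seeing the data; the other settings were planned. Over all settings, 5188 of 5755 values of named genes kept direction and side of the threshold, 516 lost the call, 35 gained it and 16 changed direction; for lists the counts were 3034 of 3198, 96, 64 and 4, where 86 values of lists that passed in neither setting changed direction and count as kept. The 16 and 4 changes of direction came with normexp alone, whose fitted background differed between arrays: the 1st percentile of kept probes then ran from -1.62 to -3.95, against -6.68 to -6.99 for the processed signal. Normexp left 40 higher and 13 lower genes for smoke, 12 and 16 for genotype, and 89 and 92 for mutant smoke against room air, with 45, 25 and 111 of at least 1.5-fold, an odds ratio near Rora of 4.43 (p = 0.0834), and a correlation of the 2 effects of -0.647; it moved the median of all genes by -0.0735, 0.101 and 0.0778 log2 units in the 3 comparisons. Before that shift is taken off, the values that turned were Ntm 0.32, Zfp663 0.26, Lingo1 0.38, Gp2 0.10, Egr3 0.30, Wfdc12 0.14, Il17rb 0.32, Arg1 0.010, Gata1 0.40, Mmp9 0.088 and Lrriq1 0.30 for genotype, Cry1 -0.044 and Epb42 -0.26 for smoke, which had not passed, and Slc38a11 0.0046, Trat1 0.050 and Upk3a 0.071 for mutant smoke against room air. With the shift taken off, 9 of the 16 turned and 7 (Gp2, Arg1, Mmp9, Cry1, Slc38a11, Trat1 and Upk3a) did not. Lists that turned, all for genotype, had adjusted p of 0.915 (type 2 genes), 0.0259 (apoptosis and autophagy), 0.167 (endothelial) and 8.18e-05 (ribosomal proteins).

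Normexp with quantile normalization gave 330 lower genes for smoke and 99, 106 and 254 genes of at least 1.5-fold in the 3 comparisons; its offset of 50 shrinks changes of dim probes by construction. No filter on dim probes gave 294 higher and 270 lower genes for smoke and 298 and 390 for genotype. Only the 8 arrays compared, with fewer samples for the spread, gave 410 lower genes for genotype. A replicate block gave 332 lower genes for smoke (323 higher), 412 and 685 for genotype and 1123 and 1869 for mutant smoke against room air; same-number arrays correlated at a median of 0.0279, so the numbers were not taken as pairs. Slide and scan as a block were the same setting and gave 335 lower genes for smoke. A limit of at least 2-fold left 110, 101 and 262 genes by construction. With an estimated correlation 3, 0 and 5 lists passed in the 3 comparisons, and in fry 11 for smoke and 13 for genotype. Leaving out 1 array gave 275 to 459 higher and 264 to 502 lower genes for smoke, 281 to 465 and 298 to 732 for genotype with 261 to 470 of at least 1.5-fold, and 881 to 1262 higher for mutant smoke against room air. For the counts above with no cause named, the cause was not tested. The fall of Rora held in all settings, from -1.92 to -2.34, and the odds ratio near Rora passed in all but normexp alone; leaving out 1 array gave 2.603 to 3.97, the highest without WT smoke replicate 1. Signal over background limits the dim genes: a gene off in 1 group has a lower bound of its change.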

Other observations

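The counts of other divisions of the arrays for single lists, and for equal numbers of genes near Rora, were chosen after the results were seen; the counts of divisions for genes and numbers of lists were planned.

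Of 20 neutrophil markers in WT lungs, Ltf (-2.03), Lcn2 (-0.64, lost in 18 of 27 settings) and Hdc (-0.53) fell with smoke and 0 rose (5 fell adjusted over the list alone); the list did not pass (adjusted p = 0.239), its test pointing down and its median, 0.02, up. Of 47 chemokines and cytokines, Ccl11 (0.61), Ccl6 (0.45) and Cxcl5 (1.68) rose and the alarmin Il33 (-0.74), Ccl17 (-0.66) and Tgfb3 (-0.39) fell; adjusted over the list alone 4 rose and 3 fell (adjusted p = 0.737). In the mutants under smoke, Il18 (0.42) and Ccl6 (0.50) of this list rose and Cxcl14 (-0.66) and Ccl11 (-0.52) fell (adjusted p = 0.238). Of 41 proteases and inhibitors, 3 rose and 3 fell in the mutants, among them stromelysin, Mmp3 (-1.12 ± 0.10, SE), Mmp9 (-0.51) and the plasminogen activator Plat (0.55); adjusted over the list alone 8 rose and 4 fell, and the list did not pass (adjusted p = 0.171). Of 25 immediate early and heat shock genes, Egr3 (-1.38), Junb (-1.005) and Ier3 (-0.32, lost in 10 of 28 settings) fell. Adjusted over the list alone 5 fell and 2 rose, and the list did not pass in camera (adjusted p = 0.0717). With the slide as a block it passed as lower (adjusted p = 0.0117, but adjusted p = 0.596 with an estimated correlation). Its slide medians were 0.05, -0.01 and -0.44, so this rests mainly on the last slide. Of the WT smoke group that slide held replicate 3 alone. This array had the highest Egr3 (-3.70), Junb (5.40) and Ier3 (3.03) of its group. B cell markers had a median of -0.31 in the mutants with 0 of 27 genes passing in limma and 3 at an unadjusted p under 0.05 (adjusted p = 9.60e-04, but adjusted p = 0.593 with an estimated correlation). T cell markers had -0.19 with 0 of 26 passing and 1 at an unadjusted p under 0.05 (adjusted p = 0.0154, and adjusted p = 0.65 with an estimated correlation), and turned on 1 slide (0.10).

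Between smoke-exposed mutants and WT in room air, which also differ in sex-linked signal, red cell genes rose: 5 of 13 erythroid genes (8 adjusted over the list alone), such as Epb42 (1.19, well above background on 1 of 4 room-air arrays), with adjusted p = 5.90e-05 and adjusted p = 0.306 with an estimated correlation. Slide medians were 0.24, 0.26 and 1.39, and in WT smoke against room air the list had a median of 0.18 (adjusted p = 0.0233). Of 16 alveolar type 1 cell markers, 6 rose and 0 fell (10 rose adjusted over the list alone), led by Igfbp2 (0.96 ± 0.10), with adjusted p = 1.78e-05 and adjusted p = 0.16 with an estimated correlation. Of 19 club cell markers, 9 fell and 0 rose (10 fell adjusted over the list alone), such as Upk3a (-0.92) and Fmo2 (-0.57; its other probes -0.21 and -0.029), with adjusted p = 3.33e-03 and adjusted p = 0.43 with an estimated correlation. Of 15 type 17 genes, 5 rose and 0 fell, as adjusted over the list alone, among them Ccl20 (1.53), with adjusted p = 6.42e-03 and adjusted p = 0.117 with an estimated correlation. Of 26 T cell markers, Trat1 (-1.13), Icos (-0.70), Lat (-0.50) and Thy1 (-0.45) fell, as adjusted over the list alone, with adjusted p = 6.01e-05 and adjusted p = 0.52 with an estimated correlation. The call of Thy1 ended with the slide as a block and in 15 of 27 settings, and that of Lat in 2. Other lists that passed here were clock (median -0.19, adjusted p = 0.0116), type 2 immunity (-0.28, adjusted p = 0.0213), cell cycle (-0.20, adjusted p = 6.80e-03), dendritic cell (-0.21, adjusted p = 7.79e-04), interferon-stimulated (-0.17, adjusted p = 0.018), natural killer (-0.25, adjusted p = 0.0364) and B cell lists (-0.20, adjusted p = 0.0483). Adipose (0.28, adjusted p = 7.52e-03) and eosinophil and mast cell lists (0.24, adjusted p = 0.0364) passed as higher, and none of these 9 passed with an estimated correlation (adjusted p of 0.0831 to 0.704). The natural killer (adjusted p = 0.0544) and B cell lists (adjusted p = 0.06) did not pass with the slide as a block, and medians turned on 1 slide for natural killer (0.03), dendritic cell (0.04) and cell cycle lists (0.12).

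Other divisions of the 8 arrays of a comparison into 4 and 4 gave far fewer genes than the groups did. For smoke, 1 of 35 divisions, the real one, gave as many as 963 genes, and the highest other gave 0; at 1.5-fold the real 327 was reached by 1 and the highest other was 0. For genotype 1 of 35 reached 1198 genes (highest other 10) and 392 genes at 1.5-fold (highest other 5). For mutant smoke against room air 1 of 35 reached 3312 and 912 genes (highest other 2 for each). For each count the real division alone reached it, which is the smallest share that 35 divisions allow. The other divisions mix the 2 groups, so group differences enter the spread and lower their counts. They do not show what unaffected arrays would give, and chance is not excluded. The odds ratio near Rora, 2.53, was reached by 1 of 35 (highest other 0), but the other divisions gave at most 10 genes, too few to expect 1 near Rora, so this decides nothing. Taking from each division the 1198 genes with the smallest p, 1 of 35 gave an odds ratio as large as 2.53 (highest other 1.90). Chosen after the result was seen, and at the smallest share possible, this count does not exclude chance. Chance cannot be excluded for the number of lists either. In 2 comparisons other divisions reached it: 7 of 35 divisions gave as many as the 18 lists for smoke (highest other 21). For mutant smoke against room air 2 of 35 gave as many as the 22 (highest other 22). For genotype 1 of 35 reached 22 lists (highest other 21).

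Single lists differed in this respect. For smoke, aryl hydrocarbon receptor, NRF2, p53, alveolar type 2, goblet and cholesterol lists had their smallest p in the real division, 1 of 35. Cell cycle, alveolar type 1 and type 17 lists had as small a p in 3, skeletal muscle in 4, macrophage genes in 5, ciliated markers in 9 and erythroid genes in 10. Smooth muscle and glucocorticoid-responsive lists had it in 11, cardiac muscle in 12, dendritic cells in 14 and T cells in 16. For genotype, the clock, type 2 immunity, eosinophil and mast cell, skeletal muscle and cholesterol lists had it in 1 of 35 and macrophage genes in 2. Alveolar type 2 markers had as small a p in 4, cardiac and ciliated lists in 5, NRF2, club and adipose lists in 6, glucocorticoid-responsive genes in 8, goblet genes in 9 and erythroid genes in 11. Interferon-stimulated and cell cycle lists had it in 12, endothelial markers in 13, matrix and B cell lists in 15, and T cell and dendritic cell lists in 18. For mutant smoke against room air, aryl hydrocarbon receptor, NRF2, p53, macrophage, type 2 immunity, clock, goblet and glucocorticoid-responsive lists had it in 1 of 35, and club, ciliated and cholesterol lists in 2. Alveolar type 1 and eosinophil and mast cell lists had it in 3, type 17 genes in 4, erythroid genes in 8, and dendritic cell and adipose lists in 10. T cell and interferon-stimulated lists had it in 12, natural killer and cell cycle lists in 16, and B cells in 20.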
